A study of Mus musculus with 20 samples.

How the data were processed

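RNA was measured in 20 libraries of sorted mouse T cells: CD8 cells at week 1 and week 4 and CD4 cells at week 1 and week 3, 5 libraries per group. Per the labels, polyclonal cells were activated for 72 h and T cell receptor transgenic cells for 24 h, and nothing in the labels says which library came from which. No beta variable segment took more than 15.26% of segment counts in any library, whereas cells with 1 transgenic receptor would share 1 segment. Polyadenylated RNA was made into stranded libraries (NEBNext Ultra II Directional) and sequenced on a NextSeq. The deposited values are raw read counts per gene, which the authors made by aligning reads with STAR to mm10 and counting exon reads with featureCounts 1.6.3 (reversely stranded, GENCODE M12 on GRCm38, per the file headers). No option for multi-mapping or overlapping reads was set, so reads that map to several places or overlap several genes were not counted. The deposited table also holds each gene's exon length in base pairs, per the file headers the merged exons as featureCounts writes them, which was used only to match genes by length.

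The table held 49671 genes, of which 49326 could be named by a GENCODE annotation and 24868 had a count in some library. No value column was left out. Library totals ran from 13.3 to 28.3 M counts. At these depths the floor of 3 counts over a group of 5 libraries equals 0.0263 to 0.0317 CPM, and a fold against a group at 0 is given as a bound from that floor. Replicates of a group were checked for duplicates: the chi-square per degree of freedom of the 40 pairs ran from 6.31 to 154. The labels give no animal, culture or pair for a library, so replicates were numbered within each group and these numbers pair no libraries.

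Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups, TMM factors, and quasi-likelihood F tests in 1 fit of 4 group means, with Benjamini-Hochberg adjusted p under 0.05 over 13290 genes. The comparisons were CD8 week 4 against week 1, CD4 week 3 against week 1, the difference of these changes (an interaction), and CD8 against CD4 at week 1 and in the long-term groups. SE is the log2 fold change divided by the square root of F. CPM are on TMM-scaled library sizes, except those of cell type markers, which are per library total. Gene lists were written before the data were examined: 36 lists of pathways and states and 13 of markers. Of the former, 35 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 35. An estimated correlation and fry were alternatives. Which of them are described was chosen after the list tests were seen. Segment use was compared by two-sided exact permutation tests (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9.

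The genes named were set by a rule written before the data were examined, and 122 genes it names are reported; 2 others it names are not reported here. It takes 13 genes of identity, memory and proliferation in both long-term comparisons. It adds the 6 largest rises and falls per cell type, the 5 most positive and negative differences, and the 4 largest each way between cell types. These need an adjusted p under 0.05 and at least 10 CPM, and outside the difference no overlap between the libraries of the groups. Unnamed and predicted genes, pseudogenes and receptor segments were left out. It also takes up to 4 called members with the smallest adjusted p of each described list, with 1 of each direction where both were called. Genes outside the rule are said to be chosen after their values were seen.

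The tests were tested on simulated data, with changes put into the counts. At 1.5-, 2- and 4-fold they called 43.3, 65.7 and 86.4% of changed genes for CD8, 38.8, 73.1 and 92.4% for CD4, and 10.4, 43.3 and 80.3% for the difference. Only 66 or 67 genes per fold and the S phase list were changed, and genes were drawn independently. In the simulation 136 genes were called for CD8, against 4454 in the real data, so these shares need not hold for the real data. Alternatives were RLE size factors, upper-quartile factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM in 5 libraries, the libraries of 1 cell type alone, the title range as a term, each CD8 title range alone, a fit without receptor segment, mitochondrial and ribosomal protein genes, a test against 1.5-fold, each library left out in turn, and, for counts of called genes, neighbouring title numbers as a block. Segment counts, 4100 to 9036 per library, were also thinned to 4100.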

Results

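RNA was sequenced from 20 libraries of mouse T cells that had been grown in culture, in 4 groups of 5 libraries. CD8 or CD4 T cells from spleen and inguinal lymph nodes had been activated through CD3 and CD28 with 1 ng/mL IL-2 and then expanded in 10 ng/mL IL-7 and 50 ng/mL IL-15, cytokines that maintain memory T cells. The week 1 groups were collected after 4 days of expansion, the CD4 week 3 group after 18 days and the CD8 week 4 group after 25 days. All libraries came from cells sorted for a surface phenotype of central memory T cells that includes CD44, to a purity above 97%. The series title asks whether such expansion preserves central and stem memory properties. The libraries held 13.3 to 28.3 M counted reads each, with group means of 18.7 ± 5.58 (CD8 week 1), 22.9 ± 4.03 (CD8 week 4), 22.6 ± 1.91 (CD4 week 1) and 23.04 ± 0.657 M (CD4 week 3; SD, n = 5 each). Nothing in the labels says that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

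In a principal component analysis of the 1000 most variable genes, PC1 (63.8% of the variance) separated CD8 from CD4 libraries and PC2 (16.1%) separated long-term from week 1 libraries. CD4 week 3 replicate 2 lay at 5.55 on PC2, while the other CD4 week 3 libraries lay between -29.8 and -14.7 and the CD4 week 1 libraries between 14 and 40.6. CD8 week 1 replicate 3 lay at 6.16 on PC2, against 20.2 to 22.2 in the other CD8 week 1 libraries. Across both cell types, the stages were thus only narrowly apart on PC2. On PC1, CD8 week 4 replicates 1 and 2 lay at -59.9 and -64.6, and the other CD8 week 4 libraries between -29 and -23.9. Ribosomal protein genes took 6.94 ± 0.524% of the counts in CD8 week 1, 8.51 ± 0.425% in CD8 week 4, 7.43 ± 0.362% in CD4 week 1 and 9.34 ± 0.746% in CD4 week 3 libraries (SD, n = 5 each). Mitochondrially encoded genes took 1.48 ± 0.254%, 1.68 ± 0.303%, 1.52 ± 0.083% and 2.09 ± 0.473% in the same order.

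**Figure D1:**
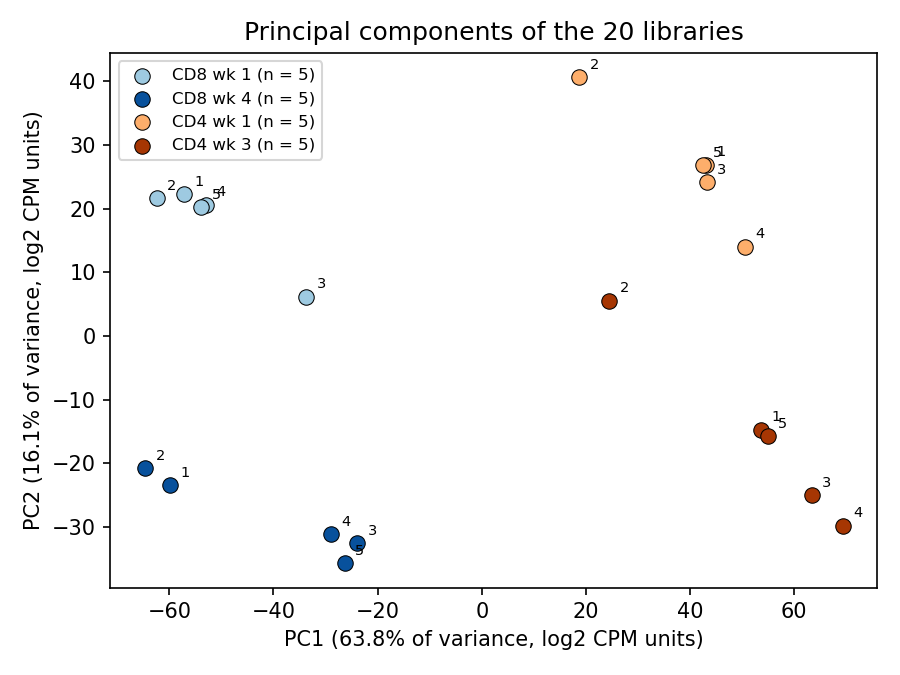
Principal components 1 (63.8% of the variance) and 2 (16.1%) of the 20 libraries, from log2 CPM of the 1000 most variable genes. Points are libraries, coloured by group (n = 5 each) and numbered by replicate; CD4 week 3 replicate 2 lies at 5.55 on PC2, above the other CD4 week 3 libraries.

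The first comparison asked how CD8 T cells changed between week 1 and week 4 of expansion. At week 4, the lists of S phase, G2 and mitosis, replication histone, cholesterol synthesis, amino acid response and transport, and inhibitory receptor genes had negative median log2 fold changes and that of ribosomal protein genes a positive one. Each of these lists passed camera's test with a preset correlation and none with an estimated one (adjusted p 0.472 to 0.64). The granzyme genes Gzmd, Gzme and Gzmg, which encode serine proteases of cytotoxic granules, rose from under 1 to between 19.4 and 51.5 CPM (counts-per-million). CD8 week 4 replicates 1 and 2 held the highest values of each, and the other week 4 libraries 3.158 to 17.2 CPM. Lef1, Foxo1, Satb1 and Bcl2, which act in naive and memory T cells, rose by 1.40- to 1.56-fold. Il7r, which encodes the alpha chain of the IL-7 receptor, was 6.01-fold lower (12.9 ± 5.09 against 77.6 ± 43.3 CPM, SD, n = 5 each). Of 13290 genes tested, 2268 were higher and 2186 lower at week 4 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 499 and 811 of them by at least 2-fold. The numbers in the titles of CD8 libraries fall into 2 ranges, A (replicates 1 to 3) and B (replicates 4 and 5). Within title range A, with 3 libraries per group, 608 genes were higher and (rounded) 4.6e+02 lower, and within title range B, with 2 per group, 1398 were higher and 1244 lower. With the title range as a term in the model, the counts were 2223 and 2157. Without CD8 week 4 replicates 1 and 2, a setting chosen after the data were seen, they were 1985 and 2015.

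Among the genes that define the sort and the memory state, most did not pass the test in CD8 cells. Libraries of both times were sorted for a central memory surface phenotype. Similar levels therefore do not show whether the unsorted cultures preserved it. Cd44 (log2 fold change -0.19, adjusted p 0.648), Cd3e (0.11, 0.409), Cd8a (0.17, 0.862), Cd8b1 (0.40, 0.489), Tcf7 (0.31, 0.309), Ccr7 (0.44, 0.232), Il2rb (0.38, 0.131) and Gzmb (-0.43, 0.477) did not pass. With only the CD8 libraries in the fit, Il2rb (0.36, adjusted p 0.0252, against 0.0252 to 0.465 over all alternatives), whose libraries did not overlap between the groups, and Gzmb (-0.45, 0.0159, against 0.0159 to 0.923) passed. Tcf7, which encodes the transcription factor TCF1, stood at 380 ± 90.6 and 472 ± 80.6 CPM, and Ccr7, a lymph node homing receptor, at 224 ± 91.4 and 303 ± 92.5 CPM. Ccr7 changed sign between the title ranges (0.91 and -0.07), as did Cd3e (0.28 and -0.16), and Cd44 stood at 0.00 and -0.47. Cd8a moved to -0.02 without CD8 week 4 replicate 3. Lef1 rose (log2 fold change 0.60, SE 0.17, adjusted p 0.0116; 133.97 ± 22.1 to 203 ± 56.4 CPM), with 0.46 and 0.76 within the title ranges (adjusted p 0.146 and 0.0156, against 0.000836 to 0.146 over all alternatives). Cd4, at 0.269 ± 0.195 CPM in week 1, had no count in any week 4 library, which makes it at least 10.1-fold lower (floor of 3 counts over the group).

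Of the 20 tested members of the naive and central memory list, 6 rose, 2 fell and 12 did not pass (6 and 3 adjusted over the list alone). The median log2 fold change was 0.38 (camera adjusted p 0.181). Foxo1 (0.63, adjusted p 0.000186), Bcl2 (0.49, 0.000477) and Satb1 (0.64, 0.00843) rose, with every week 4 library above every week 1 library. Il7r (ENSMUSG00000003882, GRCm38 chromosome 15, 9506161 to 9529876) fell (-2.59, SE 0.454, adjusted p 0.000578), by 2.72 and by 2.29 on the log2 scale within the title ranges. Within title ranges A and B, Foxo1 stood at 0.69 and 0.54, Bcl2 at 0.63 and 0.27, and Satb1 at 0.64 in both; the calls of Satb1 in either range (adjusted p 0.0997 and 0.139) and of Bcl2 in the latter (0.1) were lost, these being the highest of all alternatives for both genes. The list's median was 0.26 within title range A and 0.38 within title range B (adjusted p 0.394 and 0.0138), and 0.43 without CD8 week 4 replicates 1 and 2 (adjusted p 0.00797), over a range of 0.00797 to 0.724 in all alternatives. Of 8 stem memory genes, 1 rose, 1 fell and 6 did not pass (1 and 1 adjusted over the list alone; median 0.34, camera adjusted p 0.573; 0.22 and 0.46 within the title ranges). The member that fell was Fas, a death receptor that marks stem memory T cells (-0.83, adjusted p 0.00194; -1.09 and -0.52 within the title ranges, the latter not past the threshold at 0.148, the highest of all alternatives).

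**Figure D2:**
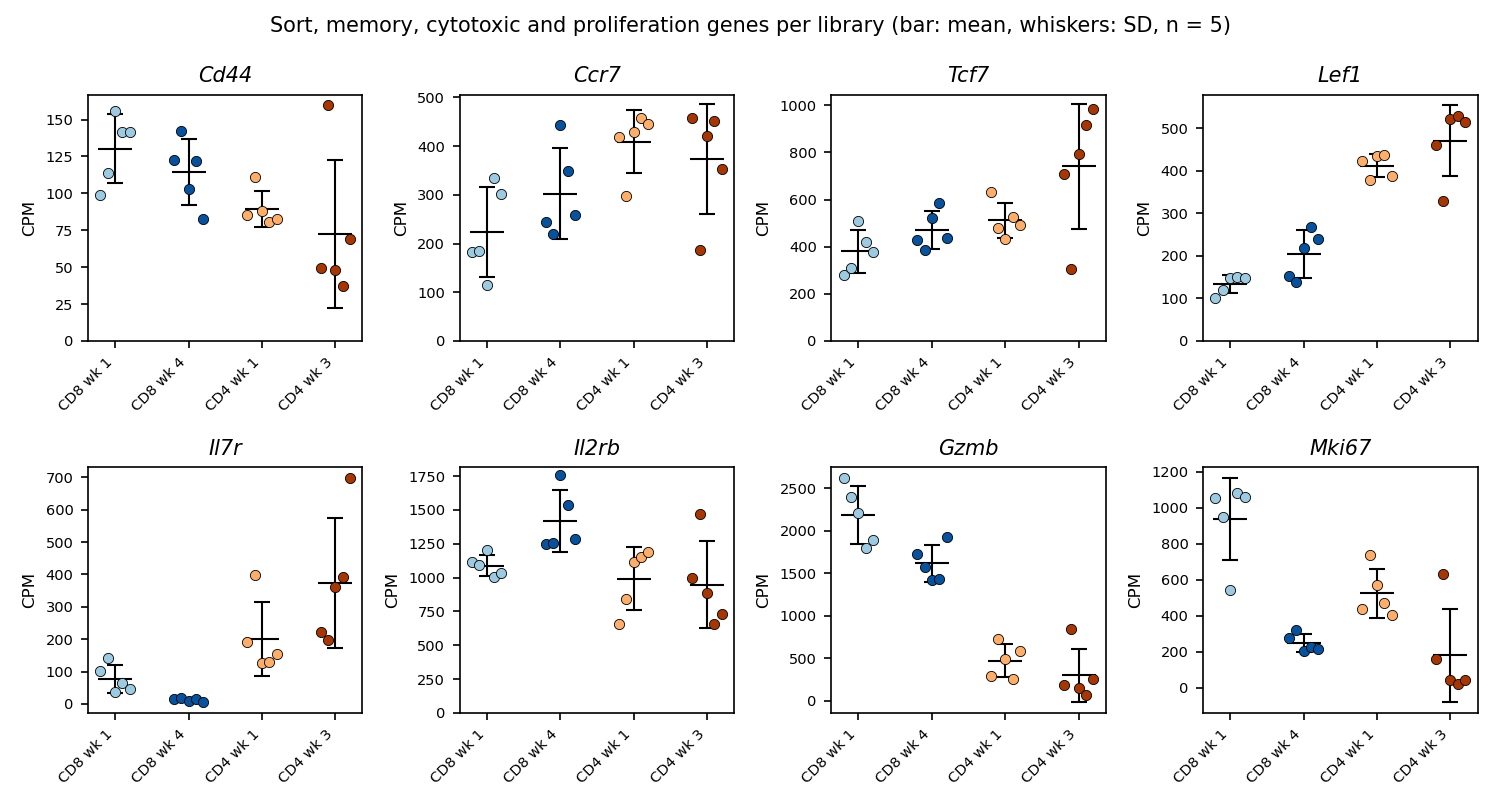
CPM of 8 genes in each library (points; bar and whiskers: mean and SD, n = 5), for CD8 week 1 and week 4 and CD4 week 1 and week 3. Il7r fell from 77.6 to 12.9 CPM in CD8 cells, and Mki67 of CD4 week 3 replicate 2 stands apart at 630.7 CPM.

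Of 23 tested effector and cytotoxic genes, 9 rose, 3 fell and 11 did not pass (9 and 3 adjusted over the list alone). The list's median was 0.45 (camera adjusted p 0.101; 0.40 and 0.48 within the title ranges), and it passed without CD8 week 1 replicate 2 (0.51, adjusted p 0.0411, against 0.0324 to 0.724 over all alternatives). Gzmg (ENSMUSG00000040284, chromosome 14, 56156582 to 56159579) rose most, from 0.179 ± 0.203 to 37.8 ± 45.2 CPM (log2 fold change 7.73, SE 0.916, adjusted p 2.24e-05; 6.74 without CD8 week 4 replicate 1 and 8.63 without CD8 week 1 replicate 2). Gzmd rose by 7.52 (6.72 without CD8 week 4 replicate 1) and Gzme by 6.63 (5.91 without it) on the log2 scale (adjusted p 4.21e-05 and 7.22e-05). Their changes within title ranges A and B were 7.80 and 7.10 (Gzmg), 8.14 and 5.64 (Gzmd) and 7.33 and 4.75 (Gzme). CD8 week 4 replicates 1 and 2 held 112.7 and 48.55 CPM of Gzmg, 139.1 and 81.55 of Gzmd and 49.76 and 32.16 of Gzme. The other week 4 libraries held 6.627 to 14.03, 7.145 to 17.2 and 3.158 to 7.183 CPM in the same order. These granzymes are near-identical neighbours, and reads that map to several of them were not counted, so the split between them is uncertain. Zeb2, a transcription factor of terminal effector cells, fell (-4.01, adjusted p 0.00108; 7.01 ± 3.3 to 0.433 ± 0.357 CPM; -3.96 and -4.16 within the title ranges). Gzmb, the most abundant of the granzymes named here, stood at 2190 ± 341 and 1620 ± 214 CPM. In the same CD8 groups, the 9 NK markers had medians of 0.417 and 0.75 CPM of the library total. The highest of them, Klrb1c, stood at 11.5 and 22.9 CPM.

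Of 18 inhibitory receptor and exhaustion genes, 9 fell and none rose in CD8 cells (9 adjusted over the list alone; median -1.37, camera adjusted p 0.000585; -1.20 and -1.51 within the title ranges). The adjusted p was 0.472 with an estimated correlation. Pdcd1, which encodes the inhibitory receptor PD-1, fell from 14 ± 6.36 to 1.25 ± 1.42 CPM (-3.50, adjusted p 0.000439; -4.29 without CD8 week 4 replicate 2; -3.08 and -5.08 within the title ranges). Tox, a transcription factor of exhausted T cells, fell by 3.03 (4.24 without CD8 week 4 replicate 5), Cd200 by 4.96 and Nr4a2 by 1.36 on the log2 scale (adjusted p 0.000585, 4.12e-06 and 0.0002), with no overlap between the libraries of the groups. Within the title ranges their changes were -3.98 and -2.36 (Tox), -6.53 and -3.53 (Cd200) and -1.16 and -1.69 (Nr4a2).

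Proliferation genes fell together. All 42 G2 and mitosis genes, 34 of 37 S phase genes and all 12 tested replication histones fell, and none rose (42, 36 and 12 adjusted over each list alone). The medians were -1.99, -1.27 and -2.15 (camera adjusted p 3.25e-13, 1.99e-11 and 4.93e-06). With an estimated correlation the adjusted p values were 0.64, 0.64 and 0.472. Within title range A the medians were -1.71, -0.99 and -1.63, and within title range B they were -2.41, -1.79 and -2.82. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a proliferation marker, fell from 937 ± 226 to 249 ± 48.3 CPM (-1.91, SE 0.625, adjusted p 0.0252). Its call was lost without CD8 week 4 replicate 4 (-1.88, adjusted p 0.0527) or replicate 5 (-1.86, 0.0534), and within either title range (-1.66 and -2.27, adjusted p 0.245 and 0.183, against 0.000127 to 0.245 over all alternatives). The kinetochore genes Cenpa and Ndc80 fell by 2.12 and 1.73, the chromatin protein gene Hmgb2 by 1.67 and the helicase gene Blm by 1.53 on the log2 scale (adjusted p 0.00064, 0.00266, 0.00266 and 0.000604). Within the title ranges they stood at -1.93 and -2.36 (Cenpa), -1.37 and -2.24 (Ndc80), -1.46 and -1.95 (Hmgb2) and -1.32 and -1.84 (Blm), where Hmgb2 missed the threshold in both ranges (adjusted p 0.0943 and 0.061) and Ndc80 in A (0.119). Of 20 p53 target and cell cycle inhibitor genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.43, camera adjusted p 0.0413). Its adjusted p was 0.724 with an estimated correlation, and the call was lost without CD8 week 1 replicate 3 (0.32, 0.176) or CD8 week 4 replicate 5 (0.39, 0.0851) and within title range A (0.30, 0.143; 0.66 within title range B). Cdkn2b, an inhibitor of cyclin-dependent kinases, rose from 1.27 ± 0.604 to 8.07 ± 2.59 CPM (2.64, adjusted p 0.000163; 2.93 and 2.34 within the title ranges).

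Of 77 ribosomal protein genes, 59 rose and none fell in CD8 cells (69 adjusted over the list alone), with a small median of 0.33 (camera adjusted p 4.56e-17; 0.26 and 0.45 within the title ranges). The adjusted p was 0.472 with an estimated correlation. Rps28 rose from 259 ± 15.2 to 400 ± 22.5 CPM (adjusted p 1.63e-05). Cholesterol synthesis genes fell in 16 of 24 cases (20 adjusted over the list alone; median -0.75, camera adjusted p 7.88e-07; -0.73 and -0.79 within the title ranges), and amino acid response and transport genes in 11 of 16 (11 adjusted over the list alone; median -0.71, camera adjusted p 4.65e-06; -0.76 and -0.68 within the title ranges). These adjusted p values were 0.64 and 0.472 with an estimated correlation. Examples were Insig1 (-1.12), a regulator of sterol synthesis, Slc7a5 (-1.32), which transports large neutral amino acids, Mthfd2 (-1.32) of mitochondrial folate metabolism, and Psat1 (-1.62) of serine synthesis (adjusted p 0.000821, 0.000138, 9.55e-06 and 0.000419). Within the title ranges they stood at -1.40 and -0.73 (Insig1, the latter with an adjusted p of 0.115), -1.35 and -1.29 (Slc7a5), -1.24 and -1.43 (Mthfd2) and -1.47 and -1.83 (Psat1). Of 76 oxidative phosphorylation genes 14 fell and none rose (7 adjusted over the list alone; median -0.14, camera adjusted p 0.000736). Its adjusted p was 0.724 with an estimated correlation. The regulatory T cell (median -1.11, 5 of 10 fell), glycolysis (-0.36, 3 of 22), TCA cycle (-0.17, 6 of 20) and activation (-0.60, 5 of 22, 1 rose) lists were called too (6, 2, 6 and 5 fell and 1 activation gene rose adjusted over the list alone; camera adjusted p 0.00209, 0.0178, 0.0292 and 0.0292). Their adjusted p values were 0.0996, 0.724, 0.724 and 0.703 with an estimated correlation.

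Outside these lists, the largest CD8 rises by the fixed rule included Tmem176b (6.05 ± 3.69 to 124 ± 33.6 CPM; 4.36, adjusted p 8.42e-06), Ppp2r2c (5.97; 5.27 without CD8 week 4 replicate 2 and 6.56 without CD8 week 1 replicate 2) and Thbs1 (5.75; 5.10 without CD8 week 4 replicate 5 and 6.48 without CD8 week 1 replicate 3). The largest falls included Batf3, a transcription factor of the AP-1 family (11.2 ± 12.2 to 0.0702 ± 0.0879 CPM; -7.08; -6.23 without CD8 week 1 replicate 2, and a ratio of 312 with a counting interval of 106 to 1520 without CD8 week 4 replicate 1, where 3 counts are left at week 4), Tnfrsf8, which encodes CD30 (-5.34; -4.60 without CD8 week 1 replicate 2), Bcat1 (-4.75) and Matk, a kinase related to Csk (-3.05). Their adjusted p values were 0.000604 (Ppp2r2c), 0.000732 (Thbs1), 0.000316 (Batf3), 0.00471 (Tnfrsf8), 0.000172 (Bcat1) and 1.31e-05 (Matk). Within title ranges A and B the log2 fold changes were 4.33 and 4.41 (Tmem176b), 6.30 and 3.62 (Ppp2r2c), 4.20 and 7.31 (Thbs1), -4.23 and -6.02 (Bcat1), -7.11 and -6.93 (Batf3), -5.16 and -5.97 (Tnfrsf8), and -3.19 and -2.84 (Matk). Ppp2r2c stood at 39.25 and 46.46 CPM in CD8 week 4 replicates 1 and 2 and at 0.7766 to 2.525 CPM in the other week 4 libraries, and its change was 2.64 (adjusted p 0.00651, against 3.82e-06 to 0.0314 over all alternatives) without both. Thbs1 missed the threshold in range A (adjusted p 0.0568) and Tnfrsf8 in both (0.095 and 0.0822). Leaving out any 1 CD8 library kept 51 of the 52 called named genes past the threshold, Mki67 being the exception.

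The second comparison asked the same of CD4 T cells between week 1 and week 3. At week 3, the lists of S phase, G2 and mitosis, replication histone, cholesterol synthesis and inhibitory receptor genes had negative median log2 fold changes and that of ribosomal protein genes a positive one, although 9 of 42 G2 and mitosis genes passed alone. Each of these lists passed camera's test with a preset correlation and none with an estimated one (adjusted p 0.435 to 0.441). Of the inhibitory receptor genes, Pdcd1 was 10.8-fold, Cd200 7.33-fold and Ctla4 2.77-fold lower. Il1rl1, which encodes the IL-33 receptor ST2, rose from 0.494 ± 0.444 to 31.2 ± 11.8 CPM (SD, n = 5 each). The memory genes Ccr7, Tcf7, Lef1 and Il7r did not pass the test. These libraries were sorted for the central memory phenotype too, so this does not show whether the unsorted cultures preserved it. Of 13290 genes, 1020 were higher and 1169 lower at week 3 (edgeR's quasi-likelihood test, adjusted p under 0.05), 318 and 449 of them by at least 2-fold. With only the CD4 libraries in the fit (rounded) 6.0e+02 were higher and 551 lower. The counts also depended on single libraries: without CD4 week 3 replicate 2 they were 1683 and 1967, without CD4 week 1 replicate 3 602 and 634, without CD4 week 3 replicate 3 596 and 516, without replicate 4 574 and 516, and without replicate 5 668 and 634. Without CD4 week 3 replicate 1, 755 genes were lower. Without CD4 week 1 replicate 2 and CD4 week 3 replicate 2 together, chosen after the data were seen, 1506 were higher and 1702 lower. CD4 libraries lie in 1 range of title numbers, so no second range could be compared.

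Ccr7 stood at 409 ± 64.8 CPM at week 1 and 374 ± 113 CPM at week 3 (log2 fold change -0.13, SE 0.274, adjusted p 0.769), Lef1 at 412 ± 27.4 and 471 ± 84.2 (0.19, 0.45), Tcf7 at 512 ± 74.6 and 741 ± 266 (0.53, 0.116) and Il7r at 200 ± 114 and 374 ± 200 CPM (0.90, 0.146). Cd44 (-0.30, adjusted p 0.494), Cd3e (-0.09, 0.537), Cd4 (-0.23, 0.422), Cd8b1 (-0.07, 0.93), Il2rb (-0.07, 0.833), Gzmb (-0.66, 0.317) and Mki67 (-1.54, 0.091) did not pass either. Without CD4 week 3 replicate 2, Mki67 (-2.97, adjusted p 0.000107), Cd44 (-0.81, 0.0028), Tcf7 (0.73, 0.00283) and Gzmb (-1.53, 0.0017) passed, and Ccr7 moved to 0.04. Il7r passed without CD4 week 1 replicate 2 (1.31, adjusted p 0.047). Over all alternatives the adjusted p of these genes ranged from 0.000107 to 0.206 (Mki67), 0.0028 to 0.798 (Cd44), 0.00283 to 0.27 (Tcf7), 0.0017 to 0.549 (Gzmb) and 0.0148 to 0.403 (Il7r). Cd8b1 changed sign without CD4 week 1 replicate 2 or CD4 week 3 replicate 3, 4 or 5, up to 0.17, and Il2rb without CD4 week 1 replicate 5 or CD4 week 3 replicate 4 or 5, up to 0.04. Cd8a, which CD4 T cells lack, rose (2.71, adjusted p 0.0382) from 0.726 ± 0.844 to 4.77 ± 7.21 CPM. CD4 week 3 replicate 1 held 17.51 CPM, and the call was lost without it (1.13, 0.281) or without CD4 week 1 replicate 3 (2.44, 0.0896), 4 (2.41, 0.0733) or 5 (2.48, 0.0783).

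Of the 20 naive and central memory genes tested in CD4 cells, none rose, 1 fell and 19 did not pass (0 and 1 adjusted over the list alone; median 0.02, camera adjusted p 0.968). With any 1 library left out the median lay between -0.03 (without CD4 week 1 replicate 2) and 0.10 (without CD4 week 1 replicate 4), and it was also negative without CD4 week 1 replicate 5 (-0.003). The member that fell was Myb, a transcription factor (-1.85, adjusted p 0.0195). Of 8 stem memory genes, 2 fell and 6 did not pass (2 adjusted over the list alone; median -0.32, camera adjusted p 0.216; -0.14 without CD4 week 1 replicate 2, -0.60 without CD4 week 3 replicate 2, -0.48 and -0.50 without CD4 week 1 replicates 4 and 5). They were Fas (-0.95, adjusted p 0.0025) and the chemokine receptor gene Cxcr3 (-1.08, 0.0247), whose call was lost without CD4 week 3 replicate 1 (0.0628) or 4 (0.0661) or CD4 week 1 replicate 2 (0.0745, the highest of all alternatives). Of 23 effector and cytotoxic genes, 2 rose, none fell and 21 did not pass (1 and 0 adjusted over the list alone; median 0.02, camera adjusted p 0.627; 0.35 without CD4 week 1 replicate 2 and -0.25 without CD4 week 3 replicate 2). They were Fasl (1.20, adjusted p 0.0182) and Prf1 (0.92, 0.0367), and of the settings that leave out 1 library Prf1 kept its call only without CD4 week 1 replicate 1 or CD4 week 3 replicate 2. With only the CD4 libraries in the fit neither passed (Fasl 1.19, adjusted p 0.0883, against 9.11e-05 to 0.0883 over all alternatives; Prf1 0.91, 0.0511, against 0.00791 to 0.144).

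Of 18 inhibitory receptor and exhaustion genes, 8 fell and none rose in CD4 cells (8 adjusted over the list alone; median -1.05, camera adjusted p 0.00195; -0.46 without CD4 week 1 replicate 2). The adjusted p was 0.441 with an estimated correlation. Pdcd1 fell from 3.30 ± 1.16 to 0.300 ± 0.168 CPM (-3.44, adjusted p 0.00305), Cd200 from 10.4 ± 3.48 to 1.42 ± 0.369 CPM (-2.87, 0.00013), Tox by 2.10 and Ctla4 by 1.47 on the log2 scale (adjusted p 0.00843 and 0.00921), with no overlap between the libraries of the groups. Of 15 NK-type receptor genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 1.37, camera adjusted p 0.000724). Its adjusted p was 0.441 with an estimated correlation. Hcst, an adaptor of the activating receptor NKG2D, rose (0.76, adjusted p 0.00191; 54.4 ± 7.47 to 92.0 ± 10.8 CPM), as did Klrd1 (1.65, 0.00479; 5.97 ± 2.66 to 18.7 ± 11.1 CPM). In the same CD4 groups the marker genes Itga2 (5.01 to 14.8), Klrb1c (0.0633 to 0.456), Tcrg-C1 (16.6 to 58.0) and Cd8a (0.716 to 4.74 CPM of the library total) had higher means at week 3. In each of these groups, 8 of 9 NK markers and 6 of 9 gamma delta T cell markers lay under 1 CPM. Klrb1f fell (-1.40, adjusted p 0.0382), a call lost without CD4 week 1 replicate 1, 2 or 3 or CD4 week 3 replicate 1, 3 or 4.

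All 35 called S phase genes, of 37 tested, fell in CD4 cells (36 adjusted over the list alone; median -1.31, camera adjusted p 6.75e-22; -1.906 without CD4 week 3 replicate 2). Of 42 G2 and mitosis genes 9 fell (37 adjusted over the list alone; median -1.54, camera adjusted p 1.40e-20; -2.92 without CD4 week 3 replicate 2), and of 12 replication histones 8 fell (10 adjusted over the list alone; median -2.01, camera adjusted p 7.19e-05). None rose, and the adjusted p of each of the 3 lists was 0.441 with an estimated correlation. The S phase genes Ccne1 (-1.24), Nasp (-0.94), Slbp (-1.0) and Hells (-1.71) fell with adjusted p between 0.00538 and 0.0083. Hells moved to -2.34 without CD4 week 3 replicate 2. The mitosis genes Hmgb2 (-1.30), Ndc80 (-1.33), Cenpa (-1.28) and Cks2 (-0.96) had adjusted p between 0.0226 and 0.0319, and each lost its call without any 1 of CD4 week 3 replicates 1, 3, 4 and 5 and CD4 week 1 replicates 2 and 3 (0.0507 to 0.0882; 2.7e-05 to 0.101 over all alternatives). With 1 library left out their changes ran from -2.004 to -1.119 (Hmgb2), -2.015 to -1.142 (Ndc80), -1.778 to -0.986 (Cenpa) and -1.416 to -0.826 (Cks2). In CD4 week 3 replicate 2, Mki67 stood at 630.7 CPM, and Hmgb2 at 347.4 CPM, near the week 1 means of 524 ± 134.3 and 339 ± 99.2 CPM. Replication histones are near-identical genes whose main transcripts lack a poly(A) tail, and the libraries were made from polyadenylated RNA. Hist1h2ab had 31 counts in all week 1 libraries together and 2 in all week 3 libraries.

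Of 77 ribosomal protein genes, 57 rose and none fell in CD4 cells (69 adjusted over the list alone; median 0.36, camera adjusted p 1.55e-26). Of 24 cholesterol synthesis genes, 19 fell and none rose (22 adjusted over the list alone; median -0.86, camera adjusted p 1.76e-12). With an estimated correlation the adjusted p values were 0.435 and 0.441. Rps28 rose from 345 ± 21.3 to 497 ± 50.6 CPM (adjusted p 0.000275), and Sqle, an enzyme of cholesterol synthesis, fell (-1.27, adjusted p 0.0125), a call lost with only the CD4 libraries in the fit (-1.275, 0.0693, against 1.25e-05 to 0.0693 over all alternatives). Of 7 tested mitochondrially encoded genes, 4 rose (6 adjusted over the list alone; median 0.55, camera adjusted p 0.004), while 17 of 76 oxidative phosphorylation genes of the nucleus fell and none rose (20 adjusted over the list alone; median -0.20, camera adjusted p 9.25e-08). These adjusted p values were 0.522 and 0.533 with an estimated correlation. The mitochondrial calls depended on single libraries: mt-Nd5 (0.79) was lost without CD4 week 3 replicate 1 (0.63, adjusted p 0.0515), mt-Nd4 (0.65) without CD4 week 1 replicate 2, 3 or 5 or CD4 week 3 replicate 1, 3 or 4, mt-Nd2 (0.63) without CD4 week 1 replicate 2 or 5 or CD4 week 3 replicate 1 or 4, and mt-Co1 (0.39) in every case but CD4 week 1 replicates 1 and 2 and CD4 week 3 replicate 2 (highest adjusted p 0.0827, 0.0844 and 0.118). Of 28 interferon response genes, 4 fell and none rose (19 adjusted over the list alone; median -1.71, camera adjusted p 0.00533). The adjusted p was 0.711 with an estimated correlation, and the call was lost without CD4 week 1 replicate 2 (-0.56, adjusted p 0.314, against 1.15e-07 to 0.711 over all alternatives), in which Isg15 stood at 286.7 CPM. Without that library Isg15 moved from -3.66 to -1.44, Zbp1 from -1.67 to -0.83, Stat2 from -1.58 to -0.63 and Igtp from -1.05 to -0.65, and none of them passed. In the same CD4 groups, the 10 MHC class II markers had a median of 5.42 CPM of the library total at week 1 and 1.02 at week 3. The highest of them, H2-DMa, stood at 50.1 and 46.1 CPM. The fatty acid synthesis (median -0.51, 1 of 11 fell), regulatory T cell (-0.49, 3 of 10) and activation (-0.24, 6 of 22) lists were called too (0, 4 and 6 fell adjusted over the list alone; camera adjusted p 0.00101, 0.0131 and 0.0315). Their adjusted p values were 0.515, 0.374 and 0.533 with an estimated correlation.

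The largest CD4 rises by the fixed rule were Fat3 (6.73; 7.45 without CD4 week 1 replicate 4), Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415; 5.97, SE 0.594), Bpifb4 (5.29; 7.05 without CD4 week 1 replicate 4), Dlg5 (4.83; 5.89 without it), Syt6 (4.68) and Kirrel (3.56). Their adjusted p values were 0.000472, 1.70e-05, 0.0125, 0.000432, 0.00985 and 0.031. The largest falls were Cd200, Klc3 (-2.51, adjusted p 7.98e-05), St3gal2 (-2.50, 0.0112), Izumo1r, which encodes folate receptor 4 (-2.49, 0.00329), Irf8, a transcription factor (-2.43, 0.00288), and Litaf (-2.26, 0.00386). The libraries of the groups did not overlap for any of these 12 genes. Leaving out any 1 CD4 library kept 33 of the 52 called named genes past the threshold in every case; of the 12, Kirrel lost its call without CD4 week 1 replicate 1, 2 or 5 or CD4 week 3 replicate 1, 3 or 4 (0.057 to 0.0692). With only the CD4 libraries in the fit, 21 of the 52 did not pass (adjusted p 0.0511 to 0.139): Cd8a, Cxcr3, Fasl, Prf1, Klrb1f, Hmgb2, Ndc80, Cenpa, Cks2, Hist1h3a, Hist1h3c, Sqle, Fdft1, Msmo1, mt-Nd4, mt-Nd2, mt-Co1, Zbp1, Isg15, Stat2 and Igtp.

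**Figure D3:**
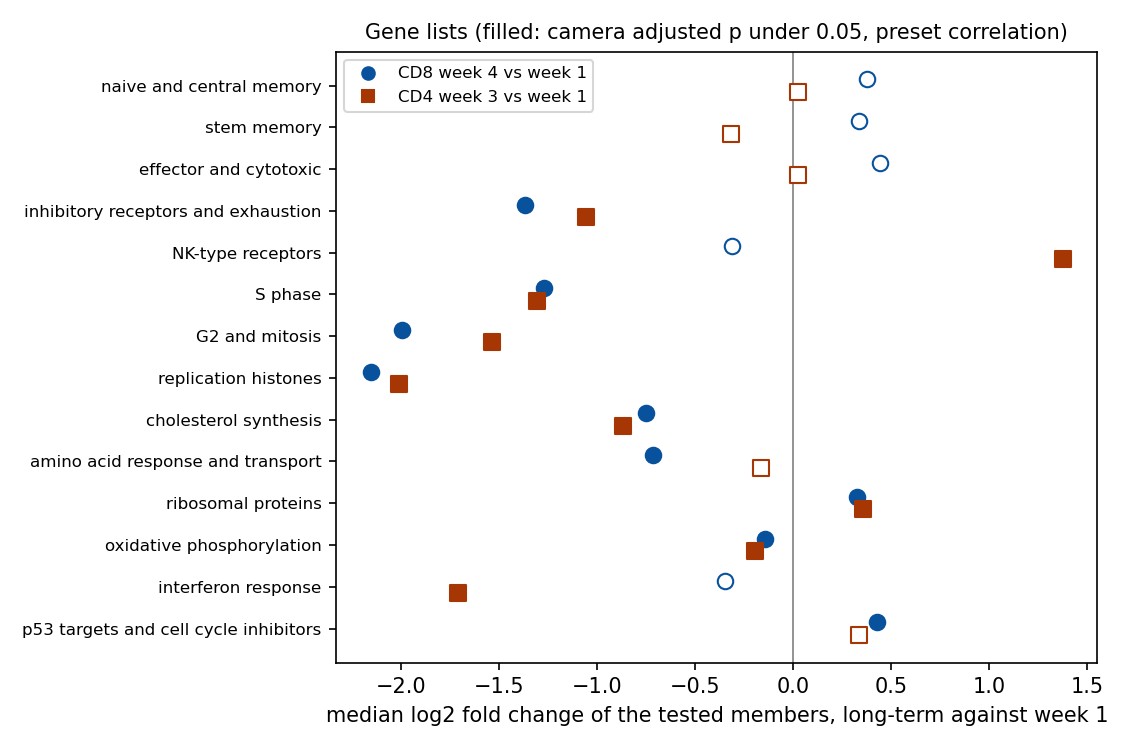
Median log2 fold change (horizontal axis) of the tested members of 14 gene lists, for CD8 week 4 against week 1 (circles) and CD4 week 3 against week 1 (squares). Filled symbols mark a camera adjusted p under 0.05 with a preset correlation; G2 and mitosis genes had medians of -1.99 and -1.54, ribosomal protein genes of 0.33 and 0.36.

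The third comparison asked whether the long-term change differed between CD8 and CD4 cells. Of 4454 genes called in CD8 and 2189 called in CD4 cells, 1484 were called in both. Of these, 1465 (98.7%) changed in the same direction, 668 higher and 797 lower in both, where independent lists would share 174 and 192. Only 6 were higher in CD8 and lower in CD4 (199 for independent lists), and 13 the reverse (168). Across all 13290 genes, called or not, 76.8% changed in the same direction, and the log2 fold changes had a Pearson r of 0.632 and a Spearman rho of 0.66, which is a correlation across genes, and genes are not independent replicates. These changes compare different libraries, but their tests share 1 fit and its estimate of the spread over all 20 libraries. The CD8 and CD4 calls are therefore not independent of each other.

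Il7r differed between the cell types, with a log2 fold change 3.49 lower in CD8 than in CD4 cells (SE 0.618, adjusted p 0.0135 for the interaction in edgeR; -3.90 to -3.14 with any 1 library left out). Gpc1, a glypican, stood at 51.2 ± 5.71 and 128 ± 27.2 CPM in CD8 cells at week 1 and week 4 and at 48.6 ± 5.7 and 33.2 ± 4.88 CPM in CD4 cells at week 1 and week 3, a difference of 1.87 (SE 0.195, adjusted p 9.36e-05). Gpr18, a G protein-coupled receptor, stood at 62.7 and 63.3 CPM in CD8 and at 44.9 and 18.8 CPM in CD4 cells (difference 1.27, adjusted p 0.00415), and the Src family kinase gene Fyn at 286 and 390 against 335 and 284 CPM (0.68, 0.018). Matk stood at 34.2 and 4.12 CPM in CD8 and 35.3 and 31.8 CPM in CD4 cells (-2.90, adjusted p 0.00473). Ptgir, a prostacyclin receptor, stood at 1.53 and 0.0850 CPM in CD8 and 41.6 and 35.7 CPM in CD4 cells (-3.93, adjusted p 0.00103). Il1rl1, which rose in CD4 cells, had 2 counts in all CD8 week 4 libraries together. The calls of Il7r, Gpc1, Gpr18, Fyn, Matk, Ptgir and Il1rl1 held without each of the 20 libraries. The difference did not pass for Tcf7 (-0.22, adjusted p 0.861), Lef1 (0.41, 0.548), Mki67 (-0.37, 0.919), Gzmb (0.22, 0.934), Gzmd (6.38, 0.124), Gzmg (6.67, 0.459), Foxo1 (0.58, 0.0541) or Pdcd1 (-0.06, 0.993).

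In total 33 genes had a higher and 54 a lower change in CD8 than in CD4 cells (11 and 44 by at least 2-fold; 1566 genes at an unadjusted p under 0.05). The counts were 156 and 178 with DESeq2, 20 and 35 with no filter, 2 and 11 against 1.5-fold, and, in settings chosen after the data were seen, 71 and 97 without CD8 week 4 replicates 1 and 2 and 75 and 103 with neighbouring title numbers as a block. They also moved with single libraries. Without CD8 week 1 replicate 3 they were 156 and 161. Both fell by over 1.5 times without CD8 week 1 replicate 1 (14 and 33), 2 (12 and 23), 4 (10 and 18) or 5 (16 and 22), CD8 week 4 replicate 1 (15 and 20) or 5 (13 and 24), CD4 week 1 replicate 1 (14 and 28), 3 (17 and 18) or 4 (13 and 25) and CD4 week 3 replicate 1 (19 and 30), 3 (15 and 27) or 4 (15 and 30), and without CD8 week 4 replicate 4 the higher count was 19. NK-type receptor genes had a median difference of -1.74 over 15 genes, 1 of them called lower and none higher (0 and 6 adjusted over the list alone; camera adjusted p 8.86e-08), and amino acid response and transport genes of -0.59 over 16, also 1 called lower (0 and 6; 1.47e-06). T cell receptor complex and signalling genes had a median difference of 0.25 over 17 genes, 2 of them called higher (2 and 0; 0.00158). With an estimated correlation the adjusted p values were 0.399, 0.399 and 0.407, and with fry 0.0665 each, so none of the 3 list calls held with either. The cell types also differed in title range and in the length of the long-term culture, so none of these differences can be assigned to the cell type alone.

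CD8 and CD4 cells were also compared at week 1. Cd8a was 1300-fold higher in CD8 cells (log2 fold change 10.347; 10.04 to 11.024 with any 1 library left out). Cd4, at 733 ± 127 CPM in CD4 cells, was 2540-fold lower in CD8 cells. The inhibitory NK receptor gene Klrc1 stood at 73.1 ± 17.4 against 0.125 ± 0.0621 CPM (log2 fold change 9.15, SE 0.401, adjusted p 1.52e-11), Klrk1, which encodes NKG2D, at 157 ± 18.3 against 0.781 ± 0.66 CPM, and the pore-forming gene Prf1 at 67.3 ± 23.2 against 5.33 ± 1.71 CPM. Lef1 was 3.08-fold lower in CD8 cells. Of 13290 genes, 2538 were higher and 2526 lower in CD8 cells (edgeR, adjusted p under 0.05), 1223 and 699 by at least 2-fold. Of 15 NK-type receptor genes 13 were higher and none lower (13 adjusted over the list alone; median 7.01, camera adjusted p 2.84e-15). This was the only list call that held with an estimated correlation, at an adjusted p of 0.0414. Of 23 effector and cytotoxic genes 16 were higher and 1 lower (16 and 1 adjusted over the list alone; median 2.36, or 2.21 with Gzmf at its bound; camera adjusted p 5.11e-07), and of 20 naive and central memory genes 1 was higher and 14 lower (1 and 15 adjusted over the list alone; median -0.87, camera adjusted p 2.82e-05). These adjusted p values were 0.394 and 0.482 with an estimated correlation. The lower cytotoxic gene was Lamp1 (-0.47, adjusted p 0.0115) and the higher naive and memory gene was Myb (1.95, 0.00408). Cd40lg, the CD40 ligand of helper T cells, was 670-fold lower in CD8 cells (-9.39, adjusted p 7.29e-12). Without CD8 week 1 replicate 2, where 3 counts are left, its ratio was 1020 (counting interval 348 to 4940). Without replicate 4, where 2 counts are left, it was 1300 (360 to 10800). St8sia6, with no count in CD8 week 1, was at least 429-fold lower in CD8 cells. Gpr141 (8.57; at least 689-fold higher without CD4 week 1 replicate 2, the only CD4 week 1 library with a count; floor of 3 counts over the other 4) and Emilin2 (8.34; 10.15 without CD4 week 1 replicate 2) were higher, and Ly6c1 was lower (-6.68; -5.96 without it).

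In the long-term groups, at week 4 for CD8 and week 3 for CD4 cells, Cd4, Klrc1, Klrk1 and Prf1 differed in the same directions. Il7r was 28.9-fold lower in CD8 cells (12.9 ± 5.09 against 374 ± 200 CPM; log2 fold change -4.85, SE 0.498, adjusted p 8.14e-07). Klrc1 was 112-fold, Klrk1 58.4-fold, Klrd1 14.2-fold and Prf1 9.47-fold higher in CD8 cells. Cd4 had no count in CD8 week 4 libraries, at least 23500-fold lower than in CD4 week 3, and Il1rl1 had a ratio of 1760 (counting interval 487 to 14500). Here 2349 genes were higher and 1993 lower in CD8 cells (edgeR, adjusted p under 0.05), 1174 and 662 by at least 2-fold. Without CD8 week 4 replicates 1 and 2 together the counts were 1383 and 1202. Of 15 NK-type receptor genes 14 were higher (14 adjusted over the list alone; median 4.66, camera adjusted p 1.25e-12; 4.059 without CD8 week 4 replicate 1), and of 23 effector and cytotoxic genes 18 (19 higher and 1 lower adjusted over the list alone; median 2.43, camera adjusted p 3.51e-11; 3.032 without CD4 week 3 replicate 2). Of 20 naive and central memory genes 1 was higher and 12 lower (1 and 13 adjusted over the list alone; median -0.61, camera adjusted p 0.000822). With an estimated correlation the adjusted p values were 0.088, 0.166 and 0.572. By the fixed rule, the genes furthest above CD4 cells in CD8 cells were Gzmg (9.14), Megf11 (8.67), Dixdc1 (8.42) and Zbtb32 (8.20). Gzmg stood at 8.16 without CD8 week 4 replicate 1. Without CD4 week 3 replicate 5, where 3 counts are left, its ratio was 1240 (counting interval 426 to 6040). Without CD4 week 3 replicate 2, where 2 counts are left, the ratio of Megf11 was 913 (253 to 7550). Dixdc1 stood at 7.70 without CD8 week 4 replicate 2 and at 4.54 without replicates 1 and 2 together. These 2 libraries held 137.5 and 160.6 CPM of Dixdc1, against 2.589 to 5.992 CPM in the other CD8 week 4 libraries. They held 92.94 and 111.3 CPM of Zbtb32, against 12.36 to 19.42 CPM in the others. Zbtb32 stood at 9.25 without CD4 week 3 replicate 2. All 19 named calls in each of these comparisons between cell types held without any 1 library.

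The use of T cell receptor beta variable segments was compared. Different clones can share a segment, so even segment use does not show that clones were evenly represented. Over 22 segments the Shannon entropy was 3.978 ± 0.009 bits in CD8 week 1 and 3.963 ± 0.013 bits in CD8 week 4 libraries (SD, n = 5; two-sided exact permutation p 0.0873 over all relabelings, adjusted p 0.349 over 4 tests), and 3.872 ± 0.026 and 3.867 ± 0.018 bits in CD4 week 1 and week 3 libraries (exact permutation p 0.754, adjusted p 0.881). The most used segment took 11.7 ± 0.919 and 11.8 ± 0.796% of segment counts in CD8 cells and 13.8 ± 0.862 and 13.6 ± 0.865% in CD4 cells (exact permutation p 0.881 and 0.762, adjusted p 0.881 for both). Without CD8 week 4 replicate 3 the CD8 entropy difference was -0.019 bits (exact permutation p 0.0238), against -0.015 with all libraries. Thinned to 4100 segment counts per library, with all libraries, it was -0.007 bits (exact permutation p 0.2857).

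Markers of other cell types differed in level. Neutrophil markers had group means of at most 0.0366 CPM of the library total (Ly6g, CD4 week 1, with 0.183 CPM in 1 library and none in the others), and Cd79b, a B cell gene, had means of 10.1 and 4.83 CPM in CD8 week 1 and week 4 and of 0.739 and 0.590 CPM in CD4 week 1 and week 3 libraries. Kit, a mast cell marker, stood at 35.1 and 21.2 CPM in CD8 week 1 and week 4 and at 1.15 and 21.1 CPM in CD4 week 1 and week 3 libraries. The NK marker Klrb1c stood at 11.5 and 22.9 CPM in CD8 week 1 and week 4 libraries. In CD4 week 1 and week 3 libraries, another NK marker, Itga2, stood at 5.01 and 14.8 CPM, and the gamma delta T cell constant gene Tcrg-C1 at 16.6 and 58.0 CPM. The highest group mean of the dendritic cell list was 16.9 CPM (Itgax, CD8 week 4), of the macrophage list 12.3 CPM (Cd68, CD8 week 1), of the erythroid list 4.33 CPM (Hba-a1, CD4 week 3), of the MHC class II list 64.2 CPM (H2-DMa, CD8 week 4) and of the stroma list 202 CPM (Pecam1, CD4 week 1). In the group named for each list, 6 of 7 dendritic cell, 10 of 13 macrophage and 8 of 10 erythroid markers lay under 1 CPM. The same held for 4 of 10 MHC class II and 7 of 9 stroma markers. Of 7 mast cell markers, 5 or 6 lay under 1 CPM in each group. Of 9 NK markers, 8 did in both CD4 groups, and 6 and 5 in CD8 week 1 and week 4. Of 9 gamma delta T cell markers, 6 did in both CD4 groups, and 4 and 5 in CD8 week 1 and week 4. The highest of these in CD8 cells, Tcrg-C2, stood at 47.1 and 37.7 CPM. Of 10 B cell markers, 9 lay under 1 CPM in both CD8 groups and all in both CD4 groups.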

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

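The tests of Il7r, of a swap of libraries, of genes past halfway, of residuals, of the scaling of ribosomal protein genes and of their change after a fit on length and expression were chosen only after the result was seen; the others were planned. For each comparison 100 splits of the libraries were counted, the real one included, and only the real split (1 of 100) reached the real number of called genes. The real and the highest other numbers were 4454 and 2914 (CD8 week 4 against week 1), 2189 and 1395 (CD4 week 3 against week 1), 87 and 4 (their difference), 5064 and 3253 (CD8 against CD4 at week 1) and 4342 and 3236 (long-term). This argues against chance for the counts within and between cell types as a whole, not for each gene. It holds only if the libraries are independent samples, which the labels do not say. For the difference the splits mix week 1 and long-term libraries, whose change then widens the spread, so they decide nothing. In limma, 110 genes were called for the difference, against 87 in edgeR. The other 99 of 100 arrangements of the residuals of a fit without a difference gave at most 0, so only the real arrangement (1 of 100) gave as many. Under the same condition, this argues against chance for the limma count as a whole.

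The long-term change differed between CD8 and CD4 cells, by the interaction test, for 16 named genes and 3 lists. On the log2 scale (CD8 minus CD4) the differences were 2.84 for Tmem176b, 2.783 for Tmem176a, 1.868 for Gpc1, 1.268 for Gpr18, 1.161 for Abi3, 0.683 for Fyn, 0.376 for Lck, -10.436 for Il1rl1, -5.423 for Cd4, -5.048 for Mctp1, -4.961 for Stc1, -4.05 for Klri2, -3.929 for Ptgir, -3.489 for Il7r, -2.901 for Matk and -1.2 for Slc7a5. The list medians were -1.736 for NK-type receptors, -0.592 for amino acid response and transport and 0.247 for the T cell receptor complex, and all 3 list calls were lost with an estimated correlation (adjusted p 0.399, 0.399 and 0.407) and with fry (0.0665 each). Il1rl1, Stc1, Cd4 and Klri2 had 0 to 3 counts in some group, so their fitted differences depend on the prior count and are no bound. In limma-voom Mctp1 (-4.339, adjusted p 0.169, against 4.61e-06 to 0.169 over its alternatives), Cd4 (-3.288, 0.0848, the highest of its alternatives), Stc1 (-3.693, 0.166) and Slc7a5 (-1.199, 0.0501) missed the threshold. Slc7a5 also missed it with library totals (0.0527), no filter (0.0647), without receptor segment, mitochondrial and ribosomal protein genes (0.053) and without CD8 week 4 replicates 1 and 2 (0.0942). Lck missed it with RLE size factors (0.0567), library totals (0.0549), no filter (0.0924), without CD8 week 4 replicates 1 and 2 (0.072) and without replicate 2 of both CD4 groups (0.0697). The latter 2 settings also ended the call of Abi3 (0.0641 and 0.063), and the former of them that of Stc1 (0.0641). Of the 20 settings that leave out 1 library, the call was lost in 13 for Tmem176b, 12 for Tmem176a, 10 for Abi3, 6 for Cd4, 11 for Stc1, 8 for Klri2, and 15 each for Slc7a5 and Lck. The highest adjusted p values were 0.0774, 0.077, 0.0693, 0.0686, 0.206, 0.0673, 0.0938 and 0.0889. In these settings the difference ran from -5.272 to -3.587 for Stc1 and from -5.393 to -3.712 for Klri2.

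Il7r fell in CD8 cells, and the change differed from that in CD4 cells. Each CD8 title range holds equal numbers of week 1 and week 4 libraries, so a shift between the ranges could not by itself give the fall in CD8 cells. A fall confined to 1 of the 2 ranges is argued against by the smaller fall of the 2, -2.291. For the difference from CD4 cells, title numbers stay open, since 0 ranges of title numbers hold libraries of both cell types. CD4 cells in the CD8 week 1 cultures are argued against as well: Cd4 stood there at 0.0367% of its CD4 level, where 32.4% would be needed. Cell type and length of culture, which the design confounds with them, stay open and untested.

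Among 376 groups of 5 values, 51 held a library far from the others (a gap above 0.71 of the range), where chance gives about 1 in 20, or 19. That rate takes the groups as independent, while many of these genes vary together. It also does not allow for groups where the other libraries had no count, such as Cd40lg in CD8 week 4 and Klri2 in CD4 week 1. Setting 51 against 19 is therefore no test. CD4 week 3 replicate 2 held 18 of the 51. In CPM these were Mki67 630.7, Hmgb2 347.4, Cenpa 103.1, Ndc80 47.62, Cks2 15.12, Ccne1 32.93, Hells 63.31, Nasp 89.17, Slbp 100.2, Sqle 141.9, Msmo1 75.71, Fdft1 50.78, Gzmb 842.4, Cd44 159.8, Isg15 14.82, Irf8 10.51 and Zbtb32 0.5276, all above the other libraries, and Gpr18 13.54, below them. CD4 week 1 replicate 2 held 11: Isg15 286.7, Il7r 398.3, Cd44 111.1, Abi3 23.75, Tmem176a 19.61, Fasl 18.16, Emilin2 1.458, Hist1h2ab 0.7055, Gpr141 0.2822 and Klri2 0.04704 above, and Ccr7 296.6 below. CD8 week 1 replicate 3 held 5: Insig1 197.3 above, and Mki67 543.6, Slc7a5 168.8, Psat1 111.8 and Cks2 15.65 below.

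The other values far from their group were Cd8a 17.51 and Lck 634.4 CPM in CD4 week 3 replicate 1, Igtp 413.8 in replicate 3, Stc1 44.46 in replicate 5, and long non-coding genes at 3.824% of counts in replicate 4. They also held Cd200 16.39 in CD4 week 1 replicate 1 and Bpifb4 5.202 in replicate 4. In CD8 week 1 they were Gpr18 50.82 in replicate 1, Gzmg 0.5363 and Gzmm 15.67 in replicate 2 and Rps28 286.1 in replicate 5. In CD8 week 4 they were Cd40lg 0.03572 in replicate 1, Gzmm 26.47 in replicate 2, Chaf1b 36.09 and Nasp 93.71 in replicate 3, and Myb 39.0 and Tox 3.57 in replicate 5.

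CD4 week 3 replicate 2 stood at week 1 levels of cell cycle genes: its position between the week 1 mean (0) and the mean of the other week 3 libraries (1) was -0.012 over 91 such genes. Over 3539 other genes, called without this library, it was 0.3, against 0.753 to 1.187 in the other week 3 libraries and -0.235 to 0.27 in the week 1 libraries. No CD4 week 1 library lay above 0.27, but every library except CD4 week 3 replicate 2 helped to choose these genes. Their positions are therefore not comparable with its own. Over genes called without the placed library, median positions ran from -0.15 to 0.304 in the week 1 libraries, against 0.167 in CD4 week 3 replicate 2. No other week 3 library was placed this way, so a swap with a CD4 week 1 library stays open. A week 1 library under a week 3 label may explain the position and stays open. Over the 3539 genes 24.2% lay past halfway to the week 3 mean in it, and 27.3% of those with at least 4-fold changes, within the ranges of 6.52 to 29.3% and 5.67 to 27.9% of the week 1 libraries, each over genes called without it. Single genes go against that label: in CPM, Il1rl1 stood at 22.69 in it and at 0 to 1.089 in the week 1 libraries, Cd200 at 1.055 and 7.292 to 16.39, Pdcd1 at 0.2638 and 2.218 to 4.892, Ctla4 at 1.671 and 14.21 to 18.67, Tox at 5.276 and 23.71 to 61.7, and Izumo1r at 7.474 and 36.29 to 92.3. These genes were named from tests that include this library, and their calls held without it too. They were chosen here after their values were seen, so they do not decide it. On PC1 this library (24.5) and its title neighbour, CD4 week 1 replicate 2 (18.7), both lay apart from the other CD4 libraries (42.4 to 69.3). A property that these 2 libraries share stays open and was not tested. A week 3 culture that divided more stays open too, untested.

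Of 77 ribosomal protein genes, 59 rose in CD8 and 57 in CD4 cells, with list medians of 0.328 and 0.358; both list calls were lost with an estimated correlation (adjusted p 0.472 and 0.435). Gene length and expression level are argued against as the whole cause by 95 other genes near them in both, whose medians were 0.108 in CD8 and -0.075 in CD4 cells. These genes were longer (median exon length 2380 against 1726 bp) and less abundant (median log2 CPM 9.33 against 9.95). After a fit on both properties over all other protein-coding genes, the ribosomal protein medians were 0.31 and 0.508. Scaling moves all genes of a library alike, so it cancels in the difference between the medians of the ribosomal protein genes and of these 95 genes within a library. In CD8 cells this difference rose by 0.38, with every week 4 library above every week 1 library (two-sided exact permutation p 0.00794), which argues against scaling as the whole cause. In CD4 cells it rose by 0.427 (two-sided exact permutation p 0.0238), which argues against scaling as the whole cause there too. This reading rests on a criterion of p under 0.05 that was chosen after the value was seen; by the first criterion, no overlap between the groups, scaling would stay open, since CD4 week 3 replicate 2, at 0.47, lay within the week 1 range of 0.318 to 0.608. Length of culture, which the groups differ in, stays open and untested.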

How the results depend on the processing

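The settings without CD8 week 4 replicates 1 and 2, without replicate 2 of CD4 week 1 and CD4 week 3, and with neighbouring title numbers as a block, were chosen only after the data were seen; all others were planned. No paired analysis by replicate number was possible because the labels share no replicate numbers between groups. With neighbouring title numbers within a cell type as a block, the counts for CD8 week 4 and CD4 week 3 against week 1 stayed within 1.5 times of those without it, and for the difference 75 genes were higher and 103 lower. The neighbours are a reading of the titles, 2 of 5 CD8 pairs and 1 of 5 CD4 pairs correlate under 0.1, and named genes and lists were not refitted with it. Of the results of named genes, each counted once per comparison, 173 of 173 kept direction and side of the threshold with DESeq2, 163 of 175 with limma-voom, 174 of 175 with RLE size factors, 175 of 175 with upper-quartile factors, 173 of 175 with library totals, 171 of 175 with no filter, 156 of 156 with the stricter filter, 162 of 163 without receptor segment, mitochondrial and ribosomal protein genes, and 60 of 60 with the title range as a term. The lower numbers were 40 of 61 with only CD4 libraries, 39 of 60 and 45 of 60 within CD8 title ranges A and B, 102 of 115 without the CD4 libraries above and 87 of 93 without the CD8 ones. With 1 library left out, 1688 of 1890 kept both, 188 lost the call, 5 gained it and 9 changed sign.

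Of 32 described list results, 7 kept their side with an estimated correlation and 25 lost their call, since correlated members widen the test; fry kept 27. With fry the interferon response list in CD4 cells (adjusted p 0.279) and the 3 lists of the difference (0.0665 each) lost their call.

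The counts of higher and lower genes that moved by over 1.5 times were as follows. For CD8 week 4 against week 1 they were 608 and (rounded) 4.6e+02 within title range A, 1398 and 1244 within title range B (the cause was not tested; range A has more libraries and the lower counts), and 211 and 278 against 1.5-fold. For CD4 week 3 against week 1 they were (rounded) 6.0e+02 and 551 with only CD4 libraries (the cause was not tested) and 74 and 43 against 1.5-fold. For the difference they were 156 and 178 with DESeq2, 20 and 35 with no filter, 2 and 11 against 1.5-fold and 71 and 97 without CD8 week 4 replicates 1 and 2. For CD8 against CD4 they were 908 and 508 at week 1 and 907 and 496 long-term against 1.5-fold, a stricter test, and 1383 and 1202 long-term without CD8 week 4 replicates 1 and 2. With 1 library left out, the CD4 counts ranged from 574 to 1683 and from 516 to 1967, and those of the difference from 10 to 156 and from 18 to 161.

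Log2 changes of genes that missed the threshold changed sign for CD8 week 4 against week 1 in Cd44 (0.001 within title range A), Cd3e (-0.161 within title range B, -0.066 without CD8 week 4 replicates 1 and 2) and Ccr7 (-0.071 within title range B), and for CD4 week 3 against week 1 in Cd8b1 (0.078 without the CD4 libraries above). With 1 library left out, Cd8a ranged from -0.018 to 0.313 in CD8 cells, and in CD4 cells Cd8b1 from -0.745 to 0.17, Ccr7 from -0.229 to 0.038 and Il2rb from -0.282 to 0.041. The cause was not tested.

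In CD8 cells the naive and central memory list gained a call within title range B (median 0.384, adjusted p 0.0138) and without CD8 week 4 replicates 1 and 2 (0.43, 0.00797), against 0.00797 to 0.724 over all alternatives. The effector list gained a call with fry (0.445, 0.0389) and DESeq2 (0.428, 0.0324), against 0.0324 to 0.724, and its median ranged from 0.363 to 0.506 with 1 library left out. In CD4 cells the sign of the test of the naive and central memory list changed with no filter (median 0.012). With 1 library left out its median ranged from -0.026 to 0.104, and that of the effector list from -0.249 to 0.354. The cause was not tested.

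Thinned to 4100 counts per library, the share of the most used beta segment differed by -0.358 points in CD8 and 0.086 in CD4 cells, the opposite sign to the unthinned values. With 1 library left out, it ranged from -0.247 to 0.4 in CD8 and from -0.41 to 0.19 in CD4 cells, and entropy from -0.019 to -0.011 and from -0.012 to 0.004 bits. Depth limits folds against a group with no count, such as Cd4 in CD8 week 4, to a bound (at least 10.1-fold lower).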

Other observations

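The tests of title numbers were chosen only after the result was seen, and the genes named in the last paragraph after their values were seen. Week 1 and long-term libraries alternate in title number, and libraries with neighbouring numbers may share an origin such as a mouse. If so, their deviations from their group means should go together. Over 120 pairings, the mean correlation across genes of neighbours was 0.222 in CD8 cells (-0.051 to 0.469; one-sided exact permutation p 0.0167) and 0.222 in CD4 cells (-0.113 to 0.441; one-sided exact permutation p 0.0667). Each CD8 neighbour pair lies within 1 title range, while most of the other pairings mix the ranges. The CD8 test therefore cannot tell a common origin of neighbours from a difference between the title ranges. Pairs of title range A correlated at 0.271, 0.469 and 0.366, and those of title range B at 0.054 and -0.051. Neither the CD8 nor the CD4 value decides on a common origin. The labels give no pairs, so neighbours were paired only in an added alternative for the counts of called genes.

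Tissue residency genes went both ways. In CD8 cells Cxcr6 (log2 fold change 1.06, adjusted p 0.0408), Itga1 (3.41, 0.00498) and Cdh1 (2.58, 0.0212) were higher at week 4, while Itgae was lower (-3.90, 0.000439). In CD4 cells Cxcr6 (1.26, adjusted p 0.0363) and Cdh1 (3.16, 0.0219) were higher and Rgs1 lower (-2.09, 0.0219) at week 3. The list as a whole did not pass (camera adjusted p 0.708 in CD8 and 0.511 in CD4 cells). In CD8 cells Il2ra, the alpha chain of the IL-2 receptor, was lower (-1.29, adjusted p 0.00158).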
